A study of Mus musculus with 40 samples.

How the data were processed

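RNA was measured by sequencing of polyadenylated transcripts in 40 libraries from C57BL/6 mice, 5 from each of 8 groups formed by 4 tissues (BAT, iWAT, eWAT and liver) and 2 exposures of 24 h, 4 °C (cold) and 30 °C (thermoneutral). The labels name TruSeq RNA v2 libraries, a kit that does not keep the strand, so counts of antisense, overlapping and near-identical genes are uncertain. Per the labels the authors used FastQC, STAR 2.7.8a, RSEM 1.3.0 and DESeq and the builds GRCm39 and GRCm38, without saying which build or tool gave which values. The deposited table holds expected counts, raw estimates per gene symbol without normalization, which were already whole numbers although RSEM gives fractions. No annotation, strand setting or filter was stated. Libraries were named by tissue, exposure and replicate number, and replicates were not pooled.

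The table had 260093 lines for 53863 symbols, 37176 of them with a count, and 50086 symbols matched the gene names of the GENCODE annotation. It was joined by symbol from a table of 35 libraries and a table of the 5 thermoneutral liver libraries, so a symbol shared by n genes stood in n times n lines. This concerned 78 symbols, in the extreme case 108900 lines for 330 genes named 7SK. Each such symbol was reduced to the sum over its genes, and these symbols held between 0.06% and 0.65% of the counts of a library. Total counts ran from 46508261 to 86681722 per library, and 0 columns were left without a sample. The depth gives counting errors far below the spread between libraries for genes at 10 CPM, and errors printed with values are standard errors of the fit or SDs between libraries, not counting intervals.

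Before the data were examined, the comparisons, tests, filters, alternatives, 24 gene lists, 13 cell type marker lists and the rule for named genes were fixed. In each tissue cold was compared with thermoneutral in R 4.3.3 with edgeR 4.0.16 by its robust quasi-likelihood F-test on the 10 libraries of the tissue. Low counts were filtered by filterByExpr (minimum count 10, minimum total count 15), library sizes were scaled by TMM, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM were computed on the TMM-scaled library sizes. Differences of the cold effect between tissues were interaction contrasts of a model with 8 group means of all 40 libraries and 20756 genes, with the same filter rule and adjustment. Genes called in the same direction in several tissues were counted against the number expected for independent lists.

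Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, for lists of at least 5 tested members, adjusted over the lists of a tissue. The test was repeated with a correlation estimated from the libraries, with which 0 lists were called in any tissue (1, 0, 0 and 2 at an unadjusted p under 0.05 in BAT, iWAT, eWAT and liver). By fry, which tests whether the genes of a list move on balance in a common direction without comparing them with other genes, 21, 4, 0 and 2 lists were called (22, 13, 9 and 10 at an unadjusted p under 0.05). Members were counted by edgeR, adjusted over all genes and over the list alone. The gene lists were thermogenic programme, cAMP-induced early genes, fatty acid oxidation, de novo lipogenesis, triglyceride synthesis, lipolysis and lipid droplets, lipoprotein and fatty acid uptake, cholesterol biosynthesis, bile acid synthesis and transport, gluconeogenesis, glycolysis and glucose uptake, ketogenesis and PPARa targets, nuclear genes of oxidative phosphorylation, mitochondrially encoded proteins, tricarboxylic acid cycle, creatine and calcium cycling, unfolded protein and integrated stress response, heat shock, circadian clock, cell cycle, interferon response, acute phase and metallothionein, extracellular matrix, and secreted hormones and growth factors. The marker lists were of adipocytes, hepatocytes, skeletal muscle, lymphocytes, macrophages, neutrophils, erythroid, endothelial, epithelial, mesothelial and Schwann cells, epididymis and pancreatic acini.

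Genes named in the text followed a rule. In each tissue it took the 6 higher and 6 lower called genes of largest change with at least 10 CPM in the higher group and no overlap between the groups, without predicted genes. It added up to 4 members of smallest p in each list called by camera, the most abundant member of each marker list, and 11 genes of interest in cold exposure. Between tissues it took the 4 genes of smallest p per contrast and the 10 genes of strongest evidence among those shared by all 4 tissues. Genes outside the rule are said to have been chosen after their values were seen.

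The procedure was tested on simulated data, with counts drawn at the dispersions of each tissue and known changes placed in 200 genes. Of genes changed 2-fold it recovered 78% in BAT, 36% in iWAT, 38% in eWAT and 60% in liver, and of genes changed 4-fold 98%, 78%, 80% and 96%. It called 8, 6, 4 and 7 genes that had not been changed. A raised gene list ranked first in each tissue, with 0 other lists called by camera at the same threshold. Genes were drawn independently of each other here, so this does not show how camera behaves with correlated genes. Random splits of the real libraries had medians of 10, 13, 10 and 9 lists called in BAT, iWAT, eWAT and liver.

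Alternatives were DESeq2 1.42.0, limma-voom with quality weights, RLE size factors, library totals as the only scaling, no low-count filter, a stricter filter (mean of 5 CPM), a replicate block, marker covariates, a threshold of 0.01, a model of all 40 libraries, and leaving out each library in turn. Alternatives without ribosomal, 7SK and mitochondrial transcripts, with spermatid markers as a covariate, without 3 eWAT libraries, and without liver cold 3 and cold 5 were added after the data were seen. Each count was also recomputed for 100 random splits of the libraries within a tissue, or 40 for differences between tissues. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Read-level files were not used here.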

Results

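The series measured messenger RNA in brown adipose tissue (BAT), inguinal white adipose tissue (iWAT), epididymal white adipose tissue (eWAT) and liver of C57BL/6 mice kept for 24 h at 4 °C (cold) or at 30 °C (thermoneutral). Each of the 8 groups held 5 libraries, 40 in all, and total counts ran from 46508261 to 86681722 per library. Transcripts of the mitochondrial genome took 26.0 ± 3.33% (SD, n = 5) of the counts in thermoneutral BAT and 22.1 ± 1.85% in cold BAT, and between 5.15% and 10.4% as group means in the other tissues. Cold was compared with thermoneutral within each tissue by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and changes are log2 fold changes of cold against thermoneutral with their standard error (SE). Levels are in CPM, counts scaled to library size, given as mean ± SD of 5 libraries. The p-values measure the spread between separate samples, and the labels do not say whether equal replicate numbers name the same mouse.

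In BAT Ucp1, the uncoupling protein of brown fat mitochondria, went from 635 ± 229 CPM at thermoneutrality to 12010 ± 1361 CPM in the cold, an 18.9-fold rise (log2 4.24 ± 0.26, adjusted p = 1.84e-07). Dio2, the deiodinase that activates thyroid hormone inside the cell, rose 86.3-fold (6.43 ± 0.51) and Gk, glycerol kinase, rose 53.7-fold (5.75 ± 0.16). Ppargc1a, a coactivator of mitochondrial biogenesis, rose 9.05-fold, and Elovl3, which elongates very long fatty acids, rose 153-fold. For each of these 5 genes every cold library lay above every thermoneutral library.

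Among called BAT genes with at least 10 CPM in the higher group and no overlap between the groups, predicted genes left aside, the largest rises were in genes close to silent at thermoneutrality. Mfsd2a, a transporter of lysophospholipids, had 0.0889 ± 0.0742 CPM there and 106 ± 40.3 CPM in the cold (10.22 ± 0.49). Cpne5 (9.92), Cyp2b10, a cytochrome P450 (9.10), Lrrc52 (8.25), Sgk2, a serine/threonine kinase (8.21), and Tacr2, a tachykinin receptor (8.10), followed. By the same limits the steepest falls were in Ntrk3, a neurotrophin receptor, from 297 ± 51.4 to 6.67 ± 3.41 CPM (-5.48 ± 0.39), and in Fer1l6 (-5.44), Snhg11 (-4.60), Cdh23, a cadherin (-4.46), Strip2 (-4.31) and Cdsn (-4.16). Lep, which encodes leptin, fell by 3.26 on the log2 scale (SE 0.41), and Fgf21 rose (4.52 ± 1.12) from 0.205 to only 4.77 ± 7.07 CPM. Among genes named for their response to low temperature, Rbm3 rose (0.84 ± 0.26) and Cirbp fell (-1.07 ± 0.15). Pdk4, which restrains pyruvate oxidation, was not called (0.17 ± 0.24, adjusted p = 0.549).

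Of all 15288 genes tested in BAT 60.2% were called, 4614 higher and 4586 lower. Counts of called list members in BAT have to be read against these shares. Of the 26 tested genes of the thermogenic programme in BAT, 16 rose and 3 fell, with the same counts when adjusted over the list alone (median 1.15). The camera test of that list gave adjusted p = 0.000521, and adjusted p = 0.473 with an estimated correlation. Triglyceride synthesis had 12 of 16 genes higher and 0 lower by edgeR (12 at an unadjusted p under 0.05), also when adjusted over the list alone, among them Dgat1, the last enzyme of the pathway (2.03 ± 0.11), and Gpam (2.01 ± 0.13). Its camera result was adjusted p = 0.00211, and adjusted p = 0.658 with an estimated correlation. Fatty acid oxidation genes were higher in 15 and lower in 6 of 26 cases (16 and 6 adjusted over the list alone). Its rising members included Cpt1a, which admits fatty acids to mitochondria (2.72 ± 0.12), Acsl1 (1.69) and Slc25a20 (1.27). Camera gave adjusted p = 0.024 for this list, and adjusted p = 0.825 with an estimated correlation.

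In the BAT list of glycolysis and glucose uptake 13 of 19 genes rose and 1 fell, equally when adjusted over the list alone, with Pfkp (1.84 ± 0.14), Pgk1 (1.26 ± 0.08) and Hk1 (1.21 ± 0.15) as examples. Camera gave adjusted p = 0.00896, and adjusted p = 0.825 with an estimated correlation. The list of ketogenesis and PPARa targets had 11 genes higher and 3 lower of 19, the same adjusted over the list alone. Bdh1, which interconverts ketone bodies, rose 177-fold (7.47 ± 0.56) and the thioesterase Acot1 rose 111-fold, whereas Angptl4, an inhibitor of lipoprotein lipase, fell (-2.40 ± 0.18). That list had a camera adjusted p = 0.0247, and adjusted p = 0.658 with an estimated correlation. In de novo lipogenesis 12 of 18 genes fell and 3 rose, unchanged when adjusted over the list alone. Fasn, fatty acid synthase, dropped from 13240 ± 5520 to 2604 ± 1374 CPM (-2.35 ± 0.43), with Pnpla3 (-3.12 ± 0.28), the citrate carrier Slc25a1 (-2.16) and Fads1 (-0.99) also lower. Camera gave adjusted p = 0.024 here, and adjusted p = 0.825 with an estimated correlation.

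3 further lists were lower in cold BAT. In the cell cycle list 15 of 25 genes fell and 1 rose, identically when adjusted over the list alone. Mcm5, of the replicative helicase, fell (-1.11 ± 0.27) at a level of a few CPM, and the riser was Tyms, thymidylate synthase (1.48 ± 0.19). Interferon response genes fell in 10 of 19 cases and rose in 0 by edgeR (12 at an unadjusted p under 0.05), and 8 fell adjusted over the list alone. The guanylate-binding proteins Gbp2 (-1.91 ± 0.28) and Gbp3 (-1.78 ± 0.33) and Ifit3 (-1.75 ± 0.36) were among them. Lymphocyte markers fell in 6 of 12 cases and rose in 0 by edgeR, also when adjusted over the list alone (7 at an unadjusted p under 0.05), at low levels such as 0.254 ± 0.0443 against 1.36 ± 1.11 CPM for the B cell gene Cd79a. Camera gave adjusted p = 0.0118, 0.0115 and 0.024 for these lists, and each had adjusted p = 0.825 with an estimated correlation.

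Markers of other tissues and cell types also differed between the BAT groups or varied within them. Among hepatocyte markers 6 of 7 fell (camera adjusted p = 0.106), and Alb, serum albumin, had 13.2 ± 10.8 CPM at thermoneutrality and 0.676 ± 0.90 in the cold. Skeletal muscle markers varied widely, with Myh4, a myosin heavy chain, at 435 ± 402 CPM in the cold and 506 ± 487 at thermoneutrality (-0.22 ± 1.19, adjusted p = 0.89). Fabp4, the most abundant adipocyte marker, rose (1.07 ± 0.10), while 2 of the 10 adipocyte markers rose and 5 fell (camera adjusted p = 0.612). Endothelial markers rose in 7 and fell in 6 of 14 cases (camera adjusted p = 0.886). Of 13 mitochondrially encoded proteins 9 fell and 1 rose, a list that camera did not call (adjusted p = 0.0694). The 27 nuclear genes of oxidative phosphorylation split into 7 higher and 6 lower (camera adjusted p = 0.811).

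Altogether 9200 of 15288 genes tested in BAT, 60.2%, had an adjusted p under 0.05, of which 4614 were higher and 4586 lower in the cold. A change over 2-fold was seen in 1472 of the higher and 1954 of the lower genes. The cold and thermoneutral libraries did not overlap for 46.4% of genes, against 0.79% by chance. The biological coefficient of variation was 24.6%.

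In iWAT the cold also brought up thermogenic genes, from a much lower start. Ucp1 rose from 2.54 ± 2.87 to 564 ± 526 CPM (7.79 ± 1.12, adjusted p = 0.00434), 222-fold. Dio2 rose 182-fold (7.51 ± 0.66), Cyp2b10 98.4-fold, Elovl3 91.1-fold, the mitochondrial carrier Slc25a34 69.8-fold and Gk 11.6-fold (3.54 ± 0.47). The cold libraries of these 6 genes all lay above the thermoneutral ones, and the SD of cold Ucp1 was close to its mean. Among called genes with at least 10 CPM in the higher group and no overlap between the groups, the steepest falls were in Sorcs2 (-2.87), the potassium channel Kcnh2 (-2.46), Acss2, which makes acetyl-CoA from acetate (-2.37), Grb14 (-2.36), the tubulin Tuba1a (-2.31) and Gamt, which completes creatine synthesis (-2.27). Ppargc1a (1.55 ± 0.34), Pdk4 (2.05 ± 0.46) and Rbm3 (0.77 ± 0.14) rose. Fasn (-1.23 ± 0.38, adjusted p = 0.0627), Angptl4 (0.20 ± 0.44), Lep (0.40 ± 0.45) and Cirbp (0.08 ± 0.13) were not called.

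4 lists of fuel oxidation and heat production were called higher in iWAT by camera, in groups that also differed in cell type markers: the mean log2 CPM of adipocyte markers was 9.92 to 10.7 at thermoneutrality and 10.68 to 11.3 in the cold, and that of lymphocyte markers averaged 4.96 and 2.11. In fatty acid oxidation 15 of 26 genes rose and 0 fell by edgeR, 19 and 1 adjusted over the list alone (21 at an unadjusted p under 0.05), with Slc25a20, the carnitine carrier (2.03 ± 0.22), Acadl (1.51 ± 0.22) and Cpt2 (1.02 ± 0.17). The tricarboxylic acid cycle had 7 of 16 genes higher and 0 lower, 12 and 0 adjusted over the list alone (12 at an unadjusted p under 0.05), including Idh3a (1.42 ± 0.27). Nuclear genes of oxidative phosphorylation rose in 6 of 27 cases and fell in 0, 22 and 0 adjusted over the list alone (22 at an unadjusted p under 0.05), such as Uqcrfs1 (1.12 ± 0.22) and Sdhd (0.87 ± 0.22). Of the thermogenic programme 9 of 23 genes rose and 2 fell, 11 and 2 adjusted over the list alone. Camera gave adjusted p = 7.33e-09, 2.75e-06, 1.24e-08 and 1.09e-05 for these 4 lists in turn. Each had adjusted p = 0.71 with an estimated correlation.

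6 lists of lipid metabolism were called in iWAT by camera. Triglyceride synthesis genes rose in 7 of 16 cases and fell in 1, 9 and 1 adjusted over the list alone, with Gpat4 (1.21 ± 0.15) and Dgat1 (1.33 ± 0.20) higher and Mogat2 (-2.84 ± 0.51) lower. For lipolysis and lipid droplets 6 of 19 rose and 2 fell, 7 and 2 adjusted over the list alone, including Pnpla2, adipose triglyceride lipase (1.39 ± 0.21), and Cidec (1.31 ± 0.18). Lipoprotein and fatty acid uptake had 2 of 20 higher, Slc27a1 (2.67 ± 0.18) and Cd36 (0.96 ± 0.24), and 0 lower by edgeR, 6 and 0 adjusted over the list alone (7 at an unadjusted p under 0.05). The list of ketogenesis and PPARa targets had 4 of 17 genes higher and 0 lower, 8 and 1 adjusted over the list alone (10 at an unadjusted p under 0.05), with Acot1 (2.88 ± 0.42) the steepest of those named. De novo lipogenesis genes fell in 6 of 18 cases and rose in 1, 11 and 1 adjusted over the list alone, with Scd2 (-2.33 ± 0.45), Acaca (-1.41 ± 0.30) and Fads2 (-1.19 ± 0.22) among them. Cholesterol biosynthesis had 6 of 24 genes lower and 0 higher, 9 and 1 adjusted over the list alone (11 at an unadjusted p under 0.05), among them the regulator Srebf2 (-0.91 ± 0.17). Camera adjusted p was 0.000201, 0.00132, 0.012, 0.025, 0.00343 and 0.00182 in that order. All 6 had adjusted p = 0.71 with an estimated correlation.

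5 further lists were called in iWAT by camera with members called in edgeR. Among cAMP-induced early genes 5 of 22 rose and 1 fell, 8 and 2 adjusted over the list alone. Nfil3 (1.80 ± 0.24), Klf9 (1.28 ± 0.19) and Per1 (1.41 ± 0.26) were higher, and Egr1 lower (-1.48 ± 0.29). Heat shock genes rose in 2 of 15 cases and fell in 1, 7 and 2 adjusted over the list alone, with the constitutive chaperone Hspa8 higher (0.75 ± 0.17) and Hsp90ab1 lower (-0.47 ± 0.12). Mitochondrially encoded proteins had 1 of 13 genes higher, mt-Nd1 (0.78 ± 0.22), and 0 lower, and 0 either way adjusted over the list alone (5 at an unadjusted p under 0.05). Adipocyte markers rose in 2 of 10 cases and fell in 0, 3 and 0 adjusted over the list alone (4 at an unadjusted p under 0.05), both risers, Fabp4 (1.56 ± 0.23) and Cidec, being lipid proteins. Interferon response genes fell in 5 of 19 cases and rose in 0, 14 and 1 adjusted over the list alone (15 at an unadjusted p under 0.05), among them Zbp1 (-1.70 ± 0.39) and Gbp2 (-0.78 ± 0.16). Camera adjusted p was 0.0233, 0.0432, 0.00532, 0.00228 and 0.000239 for these 5 lists, and all had adjusted p = 0.71 with an estimated correlation.

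3 more lists were called lower in iWAT although edgeR called 0 of their members, over all genes or adjusted over the list alone. Cell cycle genes had a median of -0.69 (6 of 25 at an unadjusted p under 0.05; Mcm5 -1.19 ± 0.37), extracellular matrix genes -0.35 (2 of 19; Lum, lumican, -1.15 ± 0.45) and lymphocyte markers -1.45 (0 of 14). Camera adjusted p was 0.00309, 0.0432 and 0.00244. With an estimated correlation the cell cycle list had adjusted p = 0.749, the matrix list adjusted p = 0.822 and the lymphocyte list adjusted p = 0.71. B cell transcripts varied widely between the libraries: Cd79a lay between 0.138 and 277 CPM, with 40.6 ± 53.7 CPM in the cold and 110 ± 95.7 at thermoneutrality (-1.43 ± 1.35), and Ms4a1 differed by -2.03 ± 1.28. Skeletal muscle was uneven too, with Myh4 at 460 ± 723 CPM in the cold and 1150 ± 2529 at thermoneutrality (-1.32 ± 2.39, adjusted p = 0.735).

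In iWAT 1926 of 16771 genes, 11.5%, passed the threshold, 1207 higher and 719 lower (751 and 987 with lymphocyte markers as a covariate), and 360 and 264 of them changed over 2-fold. The groups did not overlap for 11.3% of genes, against 0.79% by chance, and the biological coefficient of variation was 39.5%. The count was 3208 by DESeq2, 3774 by limma-voom and 1217 without the low-count filter, and 1033, 961, 1024 and 1214 without thermoneutral 2, cold 1, cold 2 or cold 5. With library totals as the only scaling 46.1% of the calls were higher in place of 62.7%, and the median of all genes was -0.16 in place of -0.05.

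**Figure D1:**
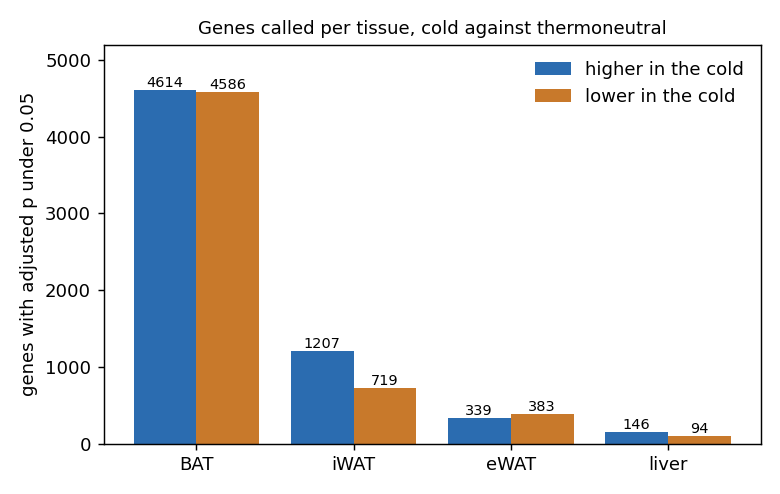
Bars count the genes with an adjusted p under 0.05 by edgeR that were higher or lower in the cold in each tissue, from 5 libraries per group, on a linear axis from 0. The higher and lower genes numbered 4614 and 4586 in BAT, 1207 and 719 in iWAT, 339 and 383 in eWAT, and 146 and 94 in liver.

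In eWAT Fasn fell from 7267 ± 2910 CPM at thermoneutrality to 1446 ± 721 CPM in the cold (-2.33 ± 0.44, adjusted p = 0.0232), and Acly, which supplies cytosolic acetyl-CoA, fell by 1.80 on the log2 scale (SE 0.38). Rbp7, a retinol-binding protein (2.53 ± 0.35), Ms4a4a (2.60 ± 0.39), Arhgef37 (2.49 ± 0.28) and Adcyap1r1, the receptor of the peptide PACAP (2.46 ± 0.37), rose most, besides Rn7s1 and Rn7s2, among called genes with at least 10 CPM in the higher group and no overlap between the groups. Within the same limits the largest falls besides Fasn and Acly were in the apelin receptor Aplnr (-2.54 ± 0.36), Pla2g2d (-2.18), Fcrls (-1.82) and Igfals (-1.80). Rn7s1 and Rn7s2, RNA genes of the signal recognition particle, had the same values (2.57 ± 0.46) and are near-identical copies, so their reads cannot be assigned to either.

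Ucp1 was too low in eWAT to be tested. Dio2 differed by 2.19 ± 0.63 (adjusted p = 0.0893), with 6.35 ± 6.24 CPM in the cold and 1.39 ± 0.63 at thermoneutrality. edgeR called 0 of the 22 tested genes of the thermogenic programme (7 at an unadjusted p under 0.05, 0 adjusted over the list alone; camera adjusted p = 0.488). Pdk4 rose (1.93 ± 0.36), while Ppargc1a (0.39 ± 0.33), Elovl3 (0.43 ± 1.19), Angptl4 (0.70 ± 0.45), Lep (0.14 ± 0.19), Cirbp (0.24 ± 0.14) and Rbm3 (0.24 ± 0.16) were not called.

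De novo lipogenesis genes fell in 5 of 19 cases in eWAT and rose in 0, 9 and 1 adjusted over the list alone (11 at an unadjusted p under 0.05), with Acaca, acetyl-CoA carboxylase, at -1.43 ± 0.33. Cholesterol biosynthesis had 4 of 24 genes lower and 0 higher, 9 and 0 adjusted over the list alone (10 at an unadjusted p under 0.05), including Idi1 (-0.73 ± 0.12) and Mvk (-0.57 ± 0.10). For lipolysis and lipid droplets 2 of 19 rose, Pnpla2 (1.48 ± 0.24) and Fabp4 (1.14 ± 0.15), and Plin3 fell (-0.41 ± 0.06), or 6 and 1 adjusted over the list alone. Among cAMP-induced early genes 3 of 22 rose and 0 fell, 5 and 1 adjusted over the list alone (9 at an unadjusted p under 0.05): Nr4a3 (2.04 ± 0.42), Klf9 (0.84 ± 0.13) and Pde3b (0.61 ± 0.13). Ketogenesis and PPARa targets had 2 of 20 genes higher, Acot2 (0.60 ± 0.08) and Pdk4, and 0 lower, 4 and 0 adjusted over the list alone (4 at an unadjusted p under 0.05). By camera the adjusted p was 0.000636, 6.03e-05, 0.0108, 0.00217 and 0.0265 for these lists. All 5 had adjusted p = 0.61 with an estimated correlation.

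2 mitochondrial lists were called higher in eWAT by camera. In fatty acid oxidation 2 of 26 genes rose, Acsl1 (1.43 ± 0.11) and Slc25a20 (0.77 ± 0.14), and 0 fell, 5 and 0 adjusted over the list alone (7 at an unadjusted p under 0.05). The mitochondrially encoded proteins had a median of 0.36 with 0 of 13 genes called over all genes or adjusted over the list alone (4 at an unadjusted p under 0.05), as in mt-Nd2 (0.50 ± 0.20). Camera gave adjusted p = 0.00593 and 0.018, and both lists had adjusted p = 0.868 with an estimated correlation.

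3 lists, of lymphocyte, interferon and cell cycle genes, were called lower in cold eWAT by camera with few members called by edgeR, while macrophage (1 higher and 1 lower; camera adjusted p = 0.403) and neutrophil markers were not. Lymphocyte markers had a median of -1.40, and Ltb, lymphotoxin beta, was the single member called (-1.47 ± 0.28); adjusted over the list alone 11 of 14 fell. Cd37 had 8.93 ± 3.04 CPM in the cold and 18.1 ± 5.54 at thermoneutrality (-1.02 ± 0.28, adjusted p = 0.0774). Interferon response genes fell in 4 of 19 cases and rose in 0, 12 and 0 adjusted over the list alone (12 at an unadjusted p under 0.05), among them Mx1 (-1.56 ± 0.35), Ifit3 (-1.48 ± 0.34) and Gbp2 (-0.86 ± 0.19). Cell cycle genes fell in 2 of 25 cases, Mcm5 (-0.94 ± 0.15) and Mcm2 (-0.67 ± 0.16), and rose in 0, 6 and 0 adjusted over the list alone (7 at an unadjusted p under 0.05). The adjusted p of camera was 7.7e-08, 1.8e-06 and 2.43e-06, and each list had adjusted p = 0.61 with an estimated correlation.

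The eWAT libraries also held transcripts of the neighbouring reproductive tract. 6 spermatid genes, chosen after their values were seen, summed to between 2.47 and 1580 CPM per library, with high and low libraries in both groups. Seminal vesicle genes, listed in the same way, summed to 747 CPM in thermoneutral 2, and epididymis genes to 3330 CPM in cold 1 and 1320 CPM in cold 4. Crisp1, an epididymal secretory protein from the lists fixed in advance, had 740 ± 1115 CPM in the cold and 8.46 ± 13.6 at thermoneutrality (6.45 ± 2.42, adjusted p = 0.184). Epithelial markers were called by camera (adjusted p = 0.0238, and adjusted p = 0.771 with an estimated correlation) with 0 of 8 members called by edgeR, 1 higher adjusted over the list alone and 2 at an unadjusted p under 0.05. Of these Krt14 differed by 2.74 ± 0.68 and Krt18 by 0.52 ± 0.51.

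In eWAT 722 of 19123 genes, 3.8%, passed the threshold, 339 higher and 383 lower, with 103 and 146 over 2-fold. The balance depended on the model, with 380 higher and 133 lower when all 40 libraries shared it and 512 and 869 by limma-voom. The groups did not overlap for 7.5% of genes, against 0.79% by chance, and the biological coefficient of variation was 53%. The count was 2101 by DESeq2, 1381 by limma-voom, 372 without the low-count filter, 125 without the 3 libraries with gland or duct transcripts (chosen after their values were seen), and 0 with the lymphocyte markers as a covariate (1465 at an unadjusted p under 0.05). The mean log2 CPM of these markers was 1.26 to 2.62 at thermoneutrality and -0.46 to 1.24 in the cold. With no overlap of the groups, that covariate cannot be told apart from exposure. Without a single library it was 299, 389, 293 and 382 (thermoneutral 1, 3, 4 and 5) or 420, 395, 391 and 300 (cold 1, 2, 4 and 5).

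In liver Dio1, the hepatic deiodinase, rose from 11.9 ± 3.2 to 90.0 ± 45.4 CPM (2.92 ± 0.39, adjusted p = 0.0322), and Mat1a, which makes S-adenosylmethionine, from 1495 ± 257 to 8028 ± 3812 CPM (2.43 ± 0.40). Got1, a transaminase (1.94 ± 0.36), Gfra1 (1.59), Idh3a (1.51) and Plin4, a lipid droplet protein (1.5), rose as well. The metallothioneins Mt1 (4.47 ± 0.90) and Mt2 (6.00 ± 1.22) rose, with cold levels of 185 ± 195 and 125 ± 159 CPM. Scd1, stearoyl-CoA desaturase, fell from 19800 ± 4637 to 6397 ± 3956 CPM (-1.63 ± 0.35). The adjusted p of the called genes named here lay close to the threshold, mostly at 0.0456.

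De novo lipogenesis genes fell in 4 of 19 cases in liver and rose in 0, 13 and 0 adjusted over the list alone (13 at an unadjusted p under 0.05). Besides Scd1 they were Pnpla3 (-3.83 ± 0.63), Acly (-1.52 ± 0.30) and Elovl5 (-0.99 ± 0.22), and Fasn was not called (-1.32 ± 0.48, adjusted p = 0.125). In gluconeogenesis 1 of 16 genes rose, Got1, and 0 fell, but 13 and 0 adjusted over the list alone (13 at an unadjusted p under 0.05), with Gpt2 at 1.01 ± 0.26. The tricarboxylic acid cycle had 2 of 16 genes higher, Idh3a and Fh1 (1.47 ± 0.30), and 0 lower, 10 and 1 adjusted over the list alone (11 at an unadjusted p under 0.05). Nuclear genes of oxidative phosphorylation had 0 of 27 members called by edgeR (10 at an unadjusted p under 0.05, 2 higher adjusted over the list alone), with Ndufs1 at 0.46 ± 0.13. In the list of acute phase proteins and metallothioneins 2 of 18 rose, both metallothioneins, and 0 fell, 4 and 0 adjusted over the list alone (7 at an unadjusted p under 0.05); Serpina3n (2.16 ± 0.54) and Lcn2 (4.89 ± 1.40) were not called. From camera came adjusted p values of 3.86e-07, 2.97e-06, 0.000124, 1.98e-05 and 7.83e-05 for the 5 lists. Each had adjusted p = 0.548 with an estimated correlation.

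Several cell type lists were called in liver by camera, in groups that also differed in ribosomal RNA. Rn18s-rs5, chosen after its values were seen, lay between 27200 and 59400 CPM of the library total in the thermoneutral libraries and at 5090, 56300, 925, 5310 and 3910 CPM in cold 1 to 5. Lymphocyte markers fell in 2 of 11 cases and rose in 0, 10 and 0 adjusted over the list alone (10 at an unadjusted p under 0.05). Cd3d, a T cell receptor component, went from 47.2 ± 40.2 CPM at thermoneutrality to 0.0684 ± 0.0475 in the cold (-9.29 ± 1.24). The ratio of Cd3d to the sum of Cd3e, Cd3g and Trac was 1.13, 0.326, 49.6, 86.9 and 8.44 in thermoneutral liver 1 to 5, against at most 0.281 in iWAT. Cd79a did not pass (-1.77 ± 0.41, adjusted p = 0.052). Cell cycle genes fell in 2 of 23 cases, Mcm3 (-1.49 ± 0.31) and Mcm2 (-1.46 ± 0.32), and rose in 0, 6 and 1 adjusted over the list alone (9 at an unadjusted p under 0.05); Rrm2 had the opposite sign (1.57 ± 0.43, adjusted p = 0.0706). Macrophage markers had 0 of 15 called (10 at an unadjusted p under 0.05, 9 lower adjusted over the list alone), with Cd68 at -1.24 ± 0.29 and C1qa at -1.17 ± 0.30. Extracellular matrix genes had 0 of 18 called (11 at an unadjusted p under 0.05, 6 lower adjusted over the list alone; Col3a1 -1.40 ± 0.40), and erythroid markers 0 of 7 (5 at an unadjusted p under 0.05, 5 lower adjusted over the list alone; Hba-a1 -1.16 ± 0.35). Mesothelial markers had 0 of 7 called (3 at an unadjusted p under 0.05, 1 higher adjusted over the list alone; Wt1 1.62 ± 0.43, below 1 CPM). The camera test gave adjusted p values of 1.39e-08, 3.5e-05, 0.00053, 0.0019, 0.00456 and 0.000259, and all 6 lists had adjusted p = 0.548 with an estimated correlation.

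4 further lists were called in liver by camera. In the interferon response 1 of 19 genes fell, Ifi27l2a (-1.84 ± 0.39), and 0 rose, 3 and 0 adjusted over the list alone (9 at an unadjusted p under 0.05). Endothelial markers had 0 of 14 called over all genes or adjusted over the list alone (3 at an unadjusted p under 0.05; Cdh5 -0.79 ± 0.34). Hepatocyte markers had 0 of 10 called (5 at an unadjusted p under 0.05, 3 higher adjusted over the list alone), with Cps1 at 1.04 ± 0.25, Tat at 1.49 ± 0.43 and Alb at 0.06 ± 0.19. Mitochondrially encoded proteins had 0 of 13 called over all genes or adjusted over the list alone (5 at an unadjusted p under 0.05; mt-Nd1 1.16 ± 0.46), and cold 3 held 21.9% mitochondrial counts against a thermoneutral mean of 6.86 ± 1.0%. By camera the adjusted p was 0.00236, 0.0158, 0.0386 and 0.0386. With an estimated correlation the interferon and endothelial lists had adjusted p = 0.632, the hepatocyte list adjusted p = 0.548 and the mitochondrially encoded list adjusted p = 0.643.

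Among called liver genes with at least 10 CPM in the higher group and no overlap, predicted genes left aside, those that fell most were Cd3d, Cd52 (-5.11 ± 0.88), the nicotinic receptor subunit Chrna4 (-4.08 ± 0.75), Tmsb10 (-3.66 ± 0.60), Cyba (-2.92 ± 0.53) and Tmsb4x (-2.7 ± 0.33, adjusted p = 0.0131). Of the genes chosen in advance Ppargc1a (1.46 ± 0.52), Angptl4 (0.93 ± 0.37), Rbm3 (0.86 ± 0.23, adjusted p = 0.0673), Cirbp (-0.17 ± 0.19), Pdk4 (-0.36 ± 0.38), Fgf21 (-0.26 ± 0.73) and Elovl3 (-0.51 ± 0.70) were not called.

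In liver 240 of 14472 genes, 1.7%, passed the threshold, 146 higher and 94 lower, with 100 and 70 over 2-fold. All thermoneutral but no cold liver libraries came from a separate table, so exposure and processing of that table cannot be told apart in these calls. The groups did not overlap for 5.45% of genes, against 0.79% by chance, and the biological coefficient of variation was 30.6%. Cold 5 lay with the thermoneutral libraries, at 0.199 on an axis from the thermoneutral mean (0) to the cold mean (1) in which each library was left out of its own group's mean and cold 5 out of all, and without it the count was 2384. It was 1652 by DESeq2, 1644 by limma-voom, 2562 when all 40 libraries shared a model, and 139 with a stricter filter. Without cold 1 or cold 4 edgeR called 0 genes (3121 and 3041 at an unadjusted p under 0.05), and with erythroid markers as a covariate 0 (2850). Without thermoneutral 1 to 5 in turn it called 5, 9, 4, 4 and 32, and without cold 2 or cold 3 it called 6 and 3. Library totals as the only scaling gave 16 calls, 31.2% of them higher in place of 60.8%, and moved the median of all genes from 0.01 to -0.16.

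**Figure D2:**
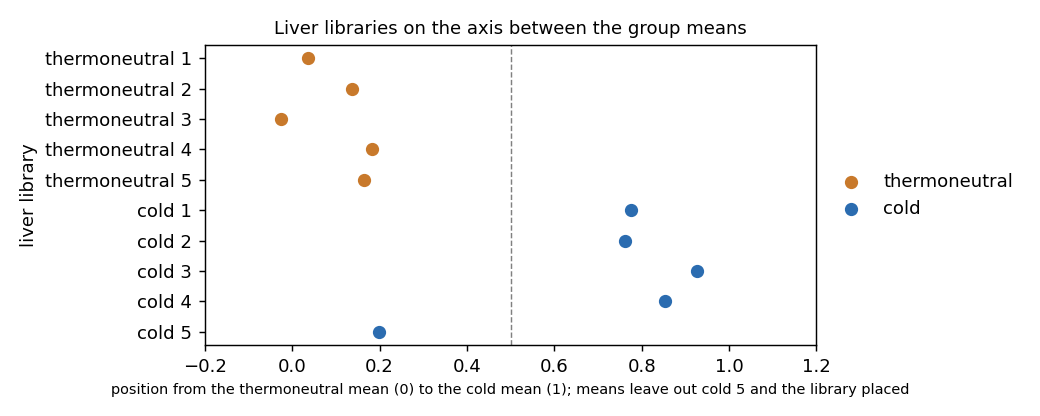
Each point is a liver library, placed on the horizontal axis by its position (no unit) from the thermoneutral mean, 0, to the cold mean, 1, where the means leave out cold 5 and the library being placed and the dashed line marks 0.5. Cold 5 lies at 0.199, near the highest thermoneutral library at 0.183, and the other cold libraries lie between 0.762 and 0.926.

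The size of the cold response differed between tissues by a test of the difference itself in a model of all 40 libraries. Between BAT and iWAT 3920 of 20756 genes differed, 2204 with the more positive effect in iWAT and 1716 with the more negative. Ctso, a cathepsin, fell in BAT (-1.79) and stood at -0.03 in iWAT, a difference of 1.82 ± 0.13, while Rom1 (3.5 and 0.08), the mitochondrial cysteinyl-tRNA synthetase Cars2 (3.47 and 0.33) and the cathepsin Ctsz (2.82 and -0.01) rose in BAT. Their differences were -3.35 ± 0.24, -3.07 ± 0.24 and -2.76 ± 0.22. With size factors by the RLE method the balance between the directions turned, to 1878 and 2051.

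Between BAT and eWAT 4767 genes differed, 2377 more positive and 2390 more negative in eWAT. Frrs1 (2.69 in BAT and 0.11 in eWAT), the peroxisomal carrier Slc25a17 (3.06 and 0.14), Cars2 (3.47 and -0.19) and Tmem82 (6.45 and -0.02) had differences of -2.53 ± 0.15, -2.87 ± 0.18, -3.61 ± 0.24 and -6.43 ± 0.45. Between BAT and liver 5005 genes differed, 2063 more positive and 2942 more negative in liver, led by Frrs1 (-2.82 ± 0.15), Slc25a17 (-3.30 ± 0.19), Sav1, a component of the Hippo pathway (-2.02 ± 0.13), and Cars2 (-3.56 ± 0.24). These 4 genes rose in BAT and lay between -0.18 and 0.05 in liver. The thermoneutral liver libraries came from a separate table, so its processing cannot be told apart from the liver effect of cold in this count.

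Between iWAT and eWAT 33 genes differed (2003 at an unadjusted p under 0.05), 24 of them with the more negative effect in eWAT. The 4 genes of smallest p were Gk, Dio2, Ucp1 and Tmem82. Gk rose in iWAT and had -0.31 in eWAT (difference -3.86 ± 0.52, adjusted p = 0.000206), and Dio2 (-5.31 ± 0.79), Ucp1 (-8.23 ± 1.22) and Tmem82 (-2.93 ± 0.43) differed likewise. Ucp1 was near the detection limit in eWAT, so the size of its difference depends on the few counts there. The count was 92 by limma-voom with a library correlation, 13 without the low-count filter and 18 without the 3 eWAT libraries with gland or duct transcripts, and it was 173 and 148 without iWAT cold 3 or cold 4 and 9 without iWAT cold 5.

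**Figure D3:**
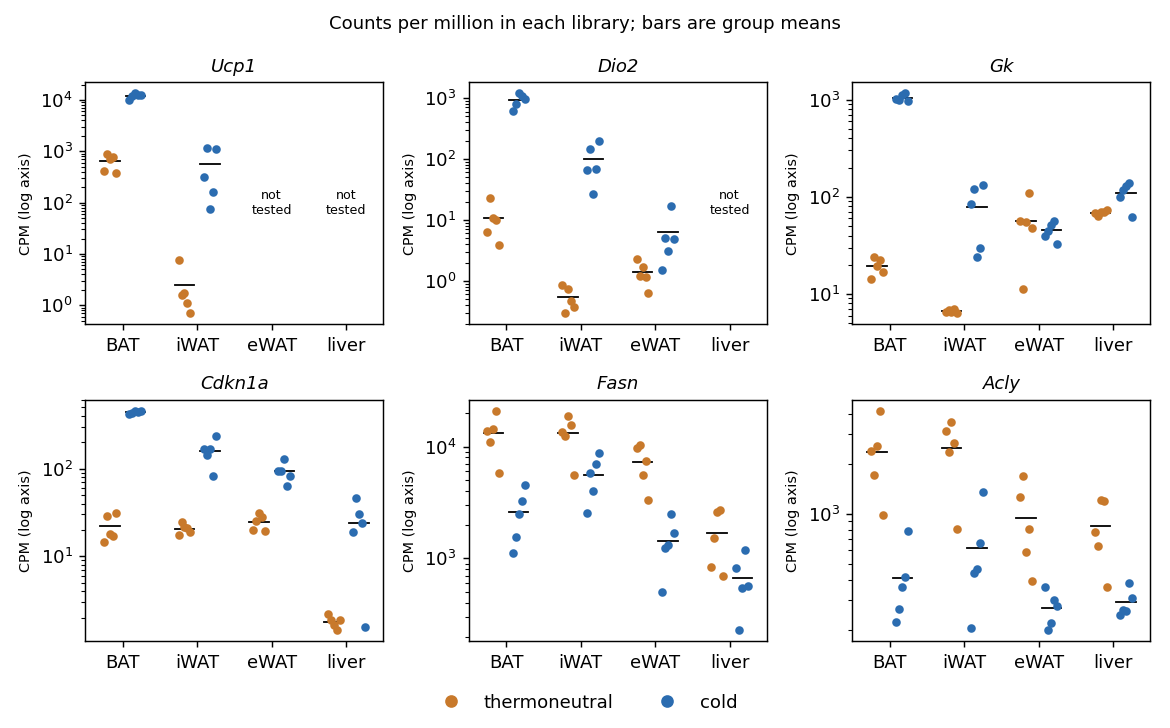
Points give the CPM of each library on a log axis for Ucp1, Dio2, Gk, Cdkn1a, Fasn and Acly in the 4 tissues, thermoneutral beside cold, and horizontal bars give the means of 5 libraries. Ucp1 averaged 12010 CPM in cold BAT and 564 CPM in cold iWAT and was not tested in eWAT and liver, where counts were too low, while Acly was lower in the cold in all 4 tissues.

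Some genes changed the same way in several tissues. Of 13142 genes tested in all 4 tissues 12 were called in the same direction in each, 10 higher and 2 lower, where independent lists would share 0.09. Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 4.33 in BAT, 2.94 in iWAT, 1.90 in eWAT and 3.74 in liver. Fkbp5, a glucocorticoid-induced cochaperone, rose by 2.62, 2.27, 0.97 and 2.43, and Ndufaf4, an assembly factor of respiratory complex I, by 1.57, 1.48, 0.63 and 1.02. Acly fell (-2.52, -2.01, -1.80 and -1.52), as did Marcks (-0.95, -0.98, -1.09 and -1.05). Without liver cold 5 the count of 12 became 70, without eWAT thermoneutral 1 it was 7, without liver thermoneutral 5 it was 2, without any other liver library it was 0, and DESeq2 gave 139.

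Over the 3 adipose depots 228 of 14762 genes changed the same way, 150 higher and 78 lower, against 12.7 for independent lists. Igfbp3 rose by 2.76, 2.00 and 1.32 in BAT, iWAT and eWAT, Sgk1, a kinase induced by glucocorticoids, by 2.28, 1.81 and 2.11, and Fabp4 by 1.07, 1.56 and 1.14. Gamt fell in each (-3.18, -2.27 and -1.25). Igfbp3 and Sgk1 were chosen after their values were seen. BAT and iWAT shared 872 higher genes (354 for independent lists) and 473 lower genes (201), and iWAT and eWAT shared 221 (24.8) and 107 (16.4). BAT and eWAT shared 208 and 195 (99.3 and 108), and with liver BAT shared 81 and 32 (38.1 and 24.0). iWAT shared 34 higher and 10 lower genes with liver (10.2 and 3.6), and eWAT 18 and 5 (2.7 and 2.1). Across genes, which are not independent replicates, the Pearson correlation of log2 fold changes was 0.492 for BAT and iWAT, 0.461 for iWAT and eWAT, 0.297 for BAT and eWAT, 0.362 for iWAT and liver, 0.285 for BAT and liver, and 0.229 for eWAT and liver.

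**Figure D4:**
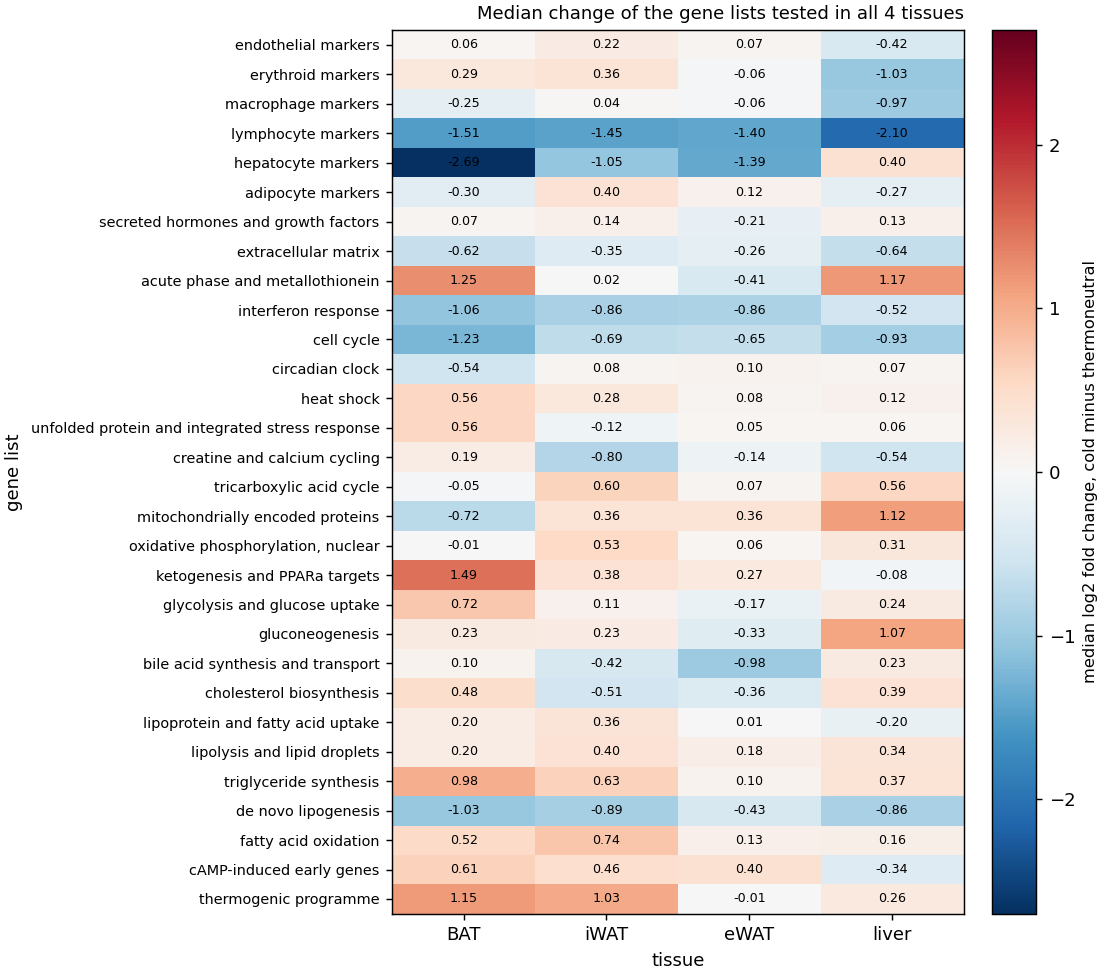
Each cell gives the median log2 fold change, cold against thermoneutral, of a gene list (vertical axis) in a tissue (horizontal axis), for the lists with at least 5 tested members in all 4 tissues. Thermogenic genes had medians of 1.15 in BAT and 1.03 in iWAT but -0.01 in eWAT, and de novo lipogenesis had a negative median in each tissue.

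Several lists were not called in a tissue. cAMP-induced early genes in BAT split into 12 higher and 6 lower of 22 (camera adjusted p = 0.171), and cholesterol biosynthesis genes into 10 and 4 of 23 (0.23). Bile acid genes were lower in 1 of 20 cases in liver and higher in 0 (9 at an unadjusted p under 0.05; camera adjusted p = 0.427), and glycolysis genes were called in 0 of 19 cases there (9 at an unadjusted p under 0.05; 0.275). Triglyceride synthesis genes were higher in 2 and lower in 2 of 16 cases in eWAT (0.276), and lower in 1 of 15 and higher in 0 in liver (8 at an unadjusted p under 0.05; 0.123). Skeletal muscle markers were not called by camera in BAT (0.57), iWAT (0.729) or eWAT (0.916), nor Schwann cell markers (0.32, 0.954 and 0.308), and of the latter 3 of 7 fell in BAT. Neutrophil markers had adjusted p = 0.752 in iWAT and 0.405 in eWAT and too few tested members elsewhere, and epididymis markers had adjusted p = 0.472 in eWAT with a median of 3.43. A single pancreatic acinar marker was tested, in liver, and was not called.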

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

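Tests of a swap and of library numbers for liver cold 5, of both T cell ratios and of repeated symbols for the liver transcripts, and both lymphocyte tests were chosen only after the results were seen, the others before.

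Liver cold 5 lay away from the other cold liver libraries in Mat1a (1840 CPM, group median 9070), Gfra1 (137 and 367), Chrna4 (9.34 and 1.52), Rrm2 (2.02 and 12.6), Angptl4 (25.5 and 95.8), Cdkn1a (1.55 and 23.8) and Fkbp5 (11.2 and 98), and at 0.199 on the axis between the groups. A swap between the liver groups needs a thermoneutral library on the cold side, but the highest thermoneutral position was 0.183, and an effect of late library numbers needs cold 4 on the thermoneutral side, but it lay at 0.853. A mouse that was not in the cold may be the source and stays open: the adipose libraries numbered cold 5 lay at 0.995 (BAT), 0.719 (iWAT) and, lowest, 0.561 (eWAT), all on the cold side, but the labels do not say whether equal numbers name a mouse. The eWAT axis also did not separate the groups, with thermoneutral libraries between 0.445 and 1.281. A sample from outside the liver groups and a weaker response of this liver were not tested.

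Several transcripts near absent in cold liver were abundant in thermoneutral liver, such as Cd3d, and Cd52 stood at 174 CPM in thermoneutral 3 (group median 21.7). T cells bring Cd3d with Cd3e, Cd3g and Trac, and the ratio of Cd3d to the sum of these 3 was at most 0.281 over the iWAT libraries. It was at least 8.44 in the 3 thermoneutral livers with over 50 CPM of Cd3d (3, 4 and 5), libraries picked by their Cd3d. This argues against T cells as the main source of Cd3d there, provided that the liver and iWAT tables counted these genes alike. In thermoneutral 1 and 2 the ratio to the sum was 1.13 and 0.326, and the lowest ratio of Cd3d to Cd3e was 3.43 (highest in iWAT 0.916), so T cells stay open in these libraries. The 5 thermoneutral liver columns came from a separate table, and another annotation or build there stays open. The count of repeated symbols held unequally by the joined tables was 0, but another release can hold the same repeats, and the number of symbols at 0 in those columns and present in all others was also 0, as for every other group, so neither test decides.

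Processing of that table and the thermoneutral group cannot be told apart, since the table holds no cold liver library. Cold 5, from the other table, was close to thermoneutral on the axis (0.199) but had, in CPM of the library total without TMM scaling, 0.145 of Cd3d, 2.45 of Cd52, 0.0544 of Gm37376 and 3910 of Rn18s-rs5, as low as in other cold livers or nearly so, and 10.6 of Chrna4, between the groups. Among the liver libraries cold 5 thus sat with its table rather than with its axis position for the first 4 of these. The exposure of cold 5 is itself in doubt, so table and exposure stay open. Rn18s-rs5 was also at 56300 CPM in cold 2, and at 34300 to 58300 CPM in the iWAT libraries of the same table, so the table alone does not set it. Without ribosomal, 7SK and mitochondrial transcripts the liver count was 237 in place of 240.

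Lymphocyte markers had negative medians in all 4 tissues (-1.51, -1.45, -1.40 and -2.10 in BAT, iWAT, eWAT and liver). In iWAT 0 of 14 members had an unadjusted edgeR p under 0.05. The liver list holds Cd3d, and its median shares the limit of the separate table. A lymph node taken with the inguinal pad in some mice is a candidate source in iWAT: the list varied 12.4-fold within the thermoneutral and 136-fold within the cold group, with Cd79a between 0.138 and 277 CPM, against at most 5.24-fold within a group in the other tissues. Fewer lymphocytes alike in all tissues with other cell types unmoved stays open: 3 lists of other cell types (macrophage, endothelial and erythroid) also had medians below -0.3 in liver, but the number of them without overlap of libraries between the groups was 0 in each tissue. A redistribution of lymphocytes in the cold, which the exposure groups would give, was not tested.

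Other libraries stood away from the 4 others of their group by a Dixon test, which flags about 1 in 20 groups by chance; 33 of 498 tests did so. In BAT these were Gbp3 in thermoneutral 1 (23.2 CPM, group median 17) and cold 2 (11.1 and 4.1), Ifit3 in thermoneutral 1 (16.7 and 8.7), Cd79a in thermoneutral 5 (3.33 and 0.868), and Hspa5 (635 and 419) and Gdf15 (52.8 and 3.44) in cold 1. In iWAT thermoneutral 5 was low for Acss2 (204 and 615), Acaca (1130 and 2360), Acly (808 and 2660) and Mogat2 (0.672 and 4.63), thermoneutral 1 differed for Gpat4 (112 and 154) and Zbp1 (40.5 and 15.2), and thermoneutral 2 for Pnpla2 (2400 and 1460). In eWAT they were Igfals in cold 1 (4.99 and 18.5), Ifit3 in thermoneutral 1 (49.7 and 19.4), Krt18 (7.25 and 53.7), Ppargc1a (5.66 and 16.5) and Cirbp (38.9 and 54.1) in thermoneutral 2, Cirbp in cold 3 (80.8 and 56.7) and Marcks in cold 2 (100 and 91.7). In liver thermoneutral 1 was high for Mt2 (5.41 and 1.07) and Lcn2 (11.7 and 1.63). The mitochondrial share was 5.13% in liver thermoneutral 1 (median 7.1%) and 21.9% in liver cold 3 (median 7.9%), and the share of the 10 most abundant genes was 16.3% in iWAT thermoneutral 1 (median 19.0%).

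The cold effect differed between tissues by the interaction test for 3920 genes (BAT and iWAT), 4767 (BAT and eWAT), 33 (iWAT and eWAT) and 5005 (BAT and liver). Named differences of log2 effects, iWAT minus BAT, were 1.82 for Ctso, -3.35 for Rom1, -3.07 for Cars2 and -2.76 for Ctsz. For eWAT minus BAT they were -2.53 for Frrs1, -2.87 for Slc25a17, -3.61 for Cars2 and -6.43 for Tmem82, and for liver minus BAT -2.82 for Frrs1, -3.30 for Slc25a17, -2.02 for Sav1 and -3.56 for Cars2. For eWAT minus iWAT they were -3.86 for Gk, -2.93 for Tmem82, -5.31 for Dio2 and -8.23 for Ucp1.

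Random splits of the libraries showed which counts chance can give. In BAT (1 of 100 splits as large, 9200 real, highest other 0) and iWAT (1, 1926, 1) chance can be excluded for the called genes. In eWAT (2, 722, 2034) and liver (3, 240, 291) few splits called as many, but each tissue had a split with more calls than the real grouping. Chance is thus unlikely there but not excluded. For the 12 shared genes (1 of 100, highest other 0, in splits with a median of 0 calls in each tissue) the splits cannot decide. No other split called a BAT gene, so none could share a gene across all 4 tissues. The eWAT split with 2034 calls parted thermoneutral 2 and 3 and cold 2, 4 and 5, the libraries with most spermatid transcripts (561 to 1580 CPM), from the rest (at most 291 CPM), which points to a structure of the samples, and the liver split with 291 exchanged cold 5 with thermoneutral 1. For the differences 1 of 40 splits was as large for BAT and iWAT (3920 real, highest other 222), BAT and eWAT (4767, 27) and BAT and liver (5005, 1673). For iWAT and eWAT it was 3 of 40 (33, 230), so chance cannot be excluded there. These splits also removed the cold effect within each tissue. A small share thus argues against chance without any cold effect, but cannot show what equal effects in both tissues would give. In the BAT and liver count the splits cannot set cold apart from the separate table of the thermoneutral livers. For the lists called by camera chance cannot be excluded in BAT (65 of 100, 9 real, highest other 15), iWAT (21, 18, 22), eWAT (48, 11, 23) or liver (6, 15, 16).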

How the results depend on the processing

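Alternatives without 3 eWAT libraries, with a spermatid covariate, without ribosomal, 7SK and mitochondrial transcripts, and without liver cold 3 and cold 5 together were chosen only after the data were seen, the others before. The BAT count stayed within 1.5 times of 9200 in every alternative tried (6577 with the stricter filter to 10010 by DESeq2; 8647 to 9554 with a library left out), whereas liver moved most. The iWAT count of 1926 became 3208 by DESeq2, 3774 by limma-voom, 1217 without the low-count filter, 392 at 0.01 and 961 to 2652 with a library left out. The eWAT count of 722 became 2101 by DESeq2, 1381 by limma-voom, 372 without the filter, 98 at 0.01, 0 by edgeR with lymphocyte markers as a covariate (1465 at an unadjusted p under 0.05), 300 without cold 5, whose library number lay apart, 125 without the 3 libraries with gland or duct transcripts, and 293 to 519 with a library left out. The lymphocyte covariate did not overlap between the eWAT groups, so it cannot be told apart from exposure. The liver count of 240 became 1652 by DESeq2, 1644 by limma-voom, 16 with library totals only, 139 with the stricter filter, 0 by edgeR with erythroid markers as a covariate (2850 at an unadjusted p under 0.05), 1861 without cold 4 and 5, 2134 without cold 3 and 5, 2562 in a model of 40 libraries, 2 at 0.01 and 0 to 2384 with a library left out (2384 without cold 5; 0 by edgeR without cold 1 or without cold 4, with 3121 and 3041 at an unadjusted p under 0.05). The 12 shared genes became 0 at 0.01, 139 by DESeq2, 71 without liver cold 3 and 5, and 0 to 70 with a library left out. Differences between tissues at 0.01 numbered 2269 (BAT and iWAT), 3128 (BAT and eWAT), 9 (iWAT and eWAT) and 3197 (BAT and liver). The 33 genes of iWAT and eWAT became 92 by limma-voom with a correlation of equal numbers, 13 without the filter, 21 without eWAT cold 5 and liver cold 4 and 5, 18 without the 3 eWAT libraries, 7 with only the 20 libraries of both tissues, and 9 to 173 with a library left out. For all of these moves the cause was not tested.

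Lists called by camera numbered 9, 18, 11 and 15 in BAT, iWAT, eWAT and liver, 0 in each with an estimated correlation (lowest adjusted p = 0.473, 0.71, 0.61 and 0.548; 1, 0, 0 and 2 at an unadjusted p under 0.05), and 21, 4, 0 and 2 by fry (22, 13, 9 and 10 at an unadjusted p under 0.05). With a library left out eWAT gave 6 to 14, and 6 without thermoneutral 3; the cause was not tested. With the replicate number as a replicate block the counts were 8609 in BAT, 108 in iWAT, 22 in eWAT and 5 in liver. The block gave 13, 20, 11 and 15 lists, and 4019, 4899, 28 and 4951 differences in the order above. Between cold and thermoneutral libraries of equal number the lowest correlation was -0.16, -0.66, -0.80 and -0.07. The numbers were therefore not read as pairs of a cold and a thermoneutral library. Mice shared across tissues are a separate question, and the main fit of the differences took all libraries as separate. Across tissues equal numbers gave a hint of shared mice at thermoneutrality in some pairs of tissues, from the data only. Between iWAT and eWAT it was 0.11 to 0.26 with 5 of 5 libraries closest to their own number, and 4 of 5 between BAT and eWAT and between BAT and liver. The other thermoneutral pairs had 2 of 5 (BAT and iWAT, iWAT and liver) and 1 of 5 (eWAT and liver, -0.07 to 0.12). The mean correlation of equal numbers was nevertheless highest for BAT and iWAT, 0.22 (0.06 to 0.58) against -0.05 for other numbers. It was 0.01 against 0 for iWAT and liver and for eWAT and liver. In the cold 0 to 3 of 5 libraries were closest to their own number, with 3 of 5 between eWAT and liver (0.01 to 0.17) and 0 of 5 between iWAT and liver. Limma-voom with a correlation of equal numbers (0.049) in place of edgeR, a change of method and of correlation, gave 4220, 5153, 92 and 4388 differences.

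Of 2279 values of named genes in the alternatives set beforehand 1938 kept direction and side of the threshold, 259 fell short of it, 72 passed it and 10 turned; with a library left out these were 2239, 383, 18 and 10 of 2650, and in added alternatives 348, 25, 13 and 1 of 387. All called genes named kept their direction in every alternative. Every library could be left out with the call kept for 69 of 69 in BAT, 43 of 52 in iWAT, 20 of 38 in eWAT and 0 of 27 in liver, and all other alternatives kept the call for 65, 12, 0 and 0. None of the genes that turned was called: Myh4 in BAT (0.05 with muscle markers as a covariate; -0.80 to 0.46 with a library left out), in iWAT Cd79a (0.50), Angptl4 (-0.37) and Lep (-0.36) with lymphocyte markers, Cirbp (-0.04) with library totals only, Angptl4 (-0.003 to 0.51) with a library left out and Myh4 in iWAT (-2.894 to 4.62, the latter without thermoneutral 3). Further ones were Cd37 in eWAT (0.021) and Lep in eWAT (-0.059) with lymphocyte markers and Elovl3 in eWAT (-0.28 to 2.37) with a library left out. In liver they were Fgf21 (0.19 without cold 4 and 5, 0.27 without cold 3 and 5, -1.33 to 0.11 with a library left out), Pdk4 (-0.56 to 0.062 with a library left out), and Alb (-0.13 with library totals only, -0.03 in the model of 40 libraries, -0.02 to 0.12 with a library left out); the cause was not tested. In simulated data 2-fold changes were found for 78% of genes in BAT, 36% in iWAT, 38% in eWAT and 60% in liver, and 4-fold changes for 98%, 78%, 80% and 96%. An uncalled gene is thus weak evidence against a 2-fold change in iWAT and eWAT. The simulated livers held no library apart from its group like cold 5. In the real liver Serpina3n and Lcn2 were not called at fitted changes over 4-fold. The liver percentages therefore do not show that an uncalled liver gene was unchanged.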

Other observations

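Genes in the next 2 paragraphs were chosen after their values were seen, from lists fixed before the data were examined, and 0 of these lists was called by camera in any tissue. In BAT 7 of 20 circadian clock genes rose and 10 fell (camera adjusted p = 0.429). The output factor Dbp fell from 59.7 ± 22.4 to 4.32 ± 0.92 CPM (-3.78 ± 0.29, n = 5 per group), Per3 fell (-3.47 ± 0.19) and so did the repressor Nr1d1 (-1.95 ± 0.15), whereas Npas2 (2.59 ± 0.21) and Nfil3 (1.94 ± 0.18) rose. In iWAT 6 clock genes rose and 1 fell, Dbp (-1.76 ± 0.34), in eWAT 1 rose and 1 fell, and in liver 0 of 20 were called by edgeR (8 at an unadjusted p under 0.05); camera adjusted p was 0.233, 0.245 and 0.302. The hours of exposure and collection were not used here. Genes of the unfolded protein and integrated stress response rose in 10 of 20 cases in BAT and fell in 1 (camera adjusted p = 0.118). Manf (2.35 ± 0.14), the chaperone Hspa5 (1.26 ± 0.13) and Calr (1.05 ± 0.08) rose, and Xbp1 fell (-0.76 ± 0.15). That list had 3 higher and 3 lower genes in iWAT, 2 and 0 in eWAT (4 at an unadjusted p under 0.05), and 0 in liver (2), with camera adjusted p = 0.719, 0.348 and 0.956.

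Among creatine and calcium cycling genes 4 of 10 rose in BAT and 2 fell (camera adjusted p = 0.429). Ckb, brain-type creatine kinase, rose from 25.9 ± 7.57 to 833 ± 160 CPM (5.01 ± 0.23) and Atp2a2, a calcium pump of the endoplasmic reticulum, rose in BAT (2.02 ± 0.08) and in iWAT (0.93 ± 0.15), while Gamt, of creatine synthesis, fell in BAT, iWAT and eWAT. The camera adjusted p of the list was 0.704, 0.931 and 0.262 in iWAT, eWAT and liver, where 1, 0 and 0 genes rose and 1, 1 and 0 fell (3, 5 and 4 at an unadjusted p under 0.05). Of the secreted hormones and growth factors 5 of 19 rose in BAT and 8 fell (camera adjusted p = 0.612; 0.93, 0.87 and 0.296 in the other tissues in the same order). Bmp8b rose from 0.168 ± 0.189 to 27.7 ± 4.53 CPM, 168-fold, and Adipoq, adiponectin, fell from 713 ± 111 to 206 ± 55.2 CPM (-1.79 ± 0.19). Gdf15 rose in BAT (4.83 ± 1.12, with 13.3 ± 22.1 CPM in the cold, 52.8 in cold 1 and a median of 3.44; 2.90 without cold 1) and fell in liver (-2.18 ± 0.47).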
